A study of Homo sapiens with 37 samples.

How the data were processed

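The data were 37 two-colour arrays of T47D cells, with RNA of unstimulated YFP cells in Cy3 and RNA of 1 of 10 groups in Cy5, per the labels' protocols. Cells were kept without hormone for 7 days, the estradiol group received 1 nM on day 6 for 24 h, and 0.85 ug of cRNA was labelled, per the labels' protocols. The values deposited by the authors were 1 normalized log ratio per probe and array, taken here as log2; blanks were probes without a value. The scanner, the normalization and the log base are not given in the sources used here. A log10 scale was excluded because the largest value, 8.83, is above the 4.82 that log10 of a 16-bit scan allows, and log2 was preferred to the natural log as the usual base for such arrays. Array medians lay between -0.042 and 0.031, so the arrays had been centred. The ratio was taken as group over YFP from the dyes and the titles, and the estrogen-induced genes of the estradiol arrays went the way this direction requires. A planned check on POLH in the POLH arrays could not be made, because no POLH probe could be named.

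Of 37974 probes, 2354 carry a RefSeq accession in their identifier. Of these, 2257 matched a gene in a RefSeq table of assembly GRCh38.p14, used for names only, and 97 did not; the remaining probes were kept under their identifiers and are not named. Probes of a gene were averaged (486 genes had several), which gave 37457 features. The 24349 with values on at least 2 arrays of every group were tested. Group and replicate came from the titles. Replicates are not said to be separate cultures, so the SD between arrays may hold labelling and hybridisation error alone, and the number of arrays limits the precision.

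A means model with 1 coefficient per group over all 37 arrays was fitted with limma 3.58.1 in R 4.3.3, so that groups of 3 to 6 arrays shared 1 moderated spread; jsonlite 2.0.0 read the labels. The mean log ratio of each group was tested against 0, and 10 differences between groups, plus that between the number-suffixed and the letter-suffixed estradiol arrays, were tested as contrasts. Tests were two-sided with Benjamini-Hochberg adjustment over features in each comparison; a feature passed at an adjusted p under 0.05 and a fold change of at least 1.5. Comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule allowed ESR1 and the fusion partners, up to 8 named genes each way with the largest change and the same sign on every array, an estrogen panel, and up to 4 members of each list with the smallest p; for differences, up to 5 genes each way. RAB6B, GSTP1 and BTN3A3 in the last part lie outside it, except GSTP1 in ESR1-YAP1.

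The 17 lists were estrogen-induced, estrogen-repressed, cell cycle, cholesterol synthesis, mesenchymal, epithelial, YAP/TEAD targets, interferon response, unfolded protein and amino acid stress response, p53 targets, ribosome biogenesis, androgen and progesterone response, AP-1 and immediate early genes, hypoxia and glycolysis, luminal markers, basal markers, and markers of other cell types. Lists with at least 5 measured genes were tested against the other named genes with camera (limma) on the moderated statistics at a preset correlation of 0.01, and again with an estimated correlation. Fry, which compares a list with no other genes, was run on the groups and is not used here. Adjustment was over the 10 groups for the estrogen-induced list, over 100 tests for the 10 other lists, and over 121 tests for the differences.

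The correlation with estradiol was Pearson's r across features between a line minus a comparator of its own suffix style and estradiol arrays of the other style minus a comparator of that style, with no array shared. The r that a line equal to YFP would give, with its log ratios set to 0, was computed beside it. Simulations of unchanged groups with 1 deviating reference, drawn 100 times for correlations and 20 times for counts, gave a level for a shared reference alone. The deviation of the reference was not estimated. It was set to the SD between arrays of each feature, and the levels depend on that choice. The steps were tested on simulated data, with 50 of 24349 features changed at each fold. For ESR1-NOP2 against YFP (3 arrays), 100% of 4-fold, 98% of 2-fold, 40% of 1.5-fold and 0% of 1.3-fold changes were recovered, with 1 false call. For YFP+E2 against YFP (6 arrays), the shares were 100%, 98%, 42% and 0%, with 0 false calls. The 1.5-fold minimum itself limits the shares at 1.5-fold and 1.3-fold, and the false calls. By the adjusted p alone, 90% and 74% of those changes passed for ESR1-NOP2, and 90% at either fold for YFP+E2. These simulations assume a reference without error.

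Alternatives were quantile normalization between arrays, arrays centred on their medians, features measured on all 37 arrays, 1 probe per gene, a fit on only the groups compared, a replicate block, fold minimums of 2 and none, suffix style as a covariate, estradiol arrays of 1 suffix style, another comparator, an estimated correlation, and leaving out each array in turn. Unnamed probes were counted but not described, since the files used here do not pair them with genes. Python with matplotlib drew the figures.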

Results

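Expression across the transcriptome was measured on 2-colour oligonucleotide arrays in T47D cells, an established line from an estrogen receptor-positive breast cancer. Lines that stably carry ESR1 fusion genes or other constructs were set against the same line carrying yellow fluorescent protein (YFP). ESR1 encodes estrogen receptor alpha, and a fusion joins part of it to a partner gene. The 37 arrays fell into 10 groups: ESR1-NOP2 (n = 3), ESR1-POLH (n = 3), ESR1-YAP1 (n = 3), ESR1-CCDC170 (n = 4), ESR1(365) (n = 4), ESR1(412) (n = 3), ESR1-PCDH11X (n = 4), POLH without ESR1 (n = 3), the ESR1 point mutant Y537S (n = 4), and YFP cells given estradiol (YFP+E2, n = 6). The titles call ESR1(365) and ESR1(412) truncations, and what the numbers 365 and 412 stand for is not given in the sources used here. Cells spent 7 days without hormone, and the estradiol group received 1 nM on day 6 for 24 h. Each array held RNA of unstimulated YFP cells in Cy3 and RNA of its group in Cy5, with no dye swap among the labels.

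An array carried values for 19728 to 31053 of 37974 probes, and each correlated with the mean of the other arrays of its group at r = 0.53 to 0.98 across probes. Only 2257 probes could be given a gene name, for 1740 genes. The test covered 24349 features, of which 1304 were named genes and 23045 were probes without a name. A feature is said to rise or fall where limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05 and the mean changed at least 1.5-fold. Values are log2 ratios of the group over YFP cells, with the SD between arrays. The log base is not stated in the sources used here, and natural logs would make every log2 ratio 1.44 times as large. None of the partners NOP2, POLH, YAP1, CCDC170 and PCDH11X had a named probe. Quantile normalization between arrays moved 50 of 350 gene results by more than 1.5-fold, 41 of them to a smaller change, as for GJA1 in ESR1 Y537S from 5.45 to 4.14 and TFF1 from 4.16 to 3.11, and WNT11 in ESR1-CCDC170 to a larger one from 1.65 to 3.16. A test against YFP leaves out the spread of the control, which was 1 sample type on every array, whereas a difference between groups cancels reference and dye.

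Estradiol set the reference response of the control cells. TFF1, a secreted trefoil peptide and a textbook estrogen target, rose by 3.85 ± 0.10 (SD, n = 6; limma adjusted p = 2.8e-34) and was higher in 6 of 6 arrays. The adrenergic receptor gene ADRA2A (3.53 ± 0.18, n = 5), the neuropeptide receptor gene NPY1R (2.89 ± 0.22, n = 6) and the peroxisomal oxidase gene ACOX2 (3.63 ± 0.11, n = 6) rose as well. The transcription factor genes MYC and MYB rose by 2.77 ± 0.11 and 1.71 ± 0.05, and the progesterone receptor gene PGR by 1.88 ± 0.06 (n = 6 each). Among genes that estrogen is known to repress, ERBB2 (-1.23 ± 0.08), CCNG2 (-0.94 ± 0.06) and TGFB3 (-0.87 ± 0.10) fell, while BMP7 (-0.46 ± 0.42, n = 5) did not pass. The immediate early gene EGR1 fell most among named genes, at -2.01 ± 0.15 (n = 6).

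Of 17 measured genes in the list of estrogen-induced genes, 12 rose and none fell after estradiol, with a mean of 1.26 (camera adjusted p = 8.87e-10). Of 32 measured cell cycle genes, 14 rose and none fell, among them the ribonucleotide reductase gene RRM2 (1.34 ± 0.09), the spindle checkpoint gene MAD2L1 (1.12 ± 0.06) and the replication clamp gene PCNA (0.99 ± 0.15). That list stood apart from the other named genes at an adjusted p of 1.1e-10. Of 8 AP-1 and immediate early genes 4 fell and 1 rose, with JUNB at -1.06 ± 0.04 and DUSP6 at -1.22 ± 0.04; the adjusted p was 0.0519, or 0.0479 with an estimated correlation. Interferon genes fell for 3 of 7 (mean -0.52), which did not pass as a set (adjusted p = 0.0624). Over all features, 1280 rose and 1421 fell. ESR1 itself, read by 3 probes, lay at the 1.5-fold minimum with 0.59 ± 0.06. It fell short with the replicate block (0.58), with only the number-suffixed estradiol arrays (0.556) and without replicate 4 (0.572).

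**Figure D1:**
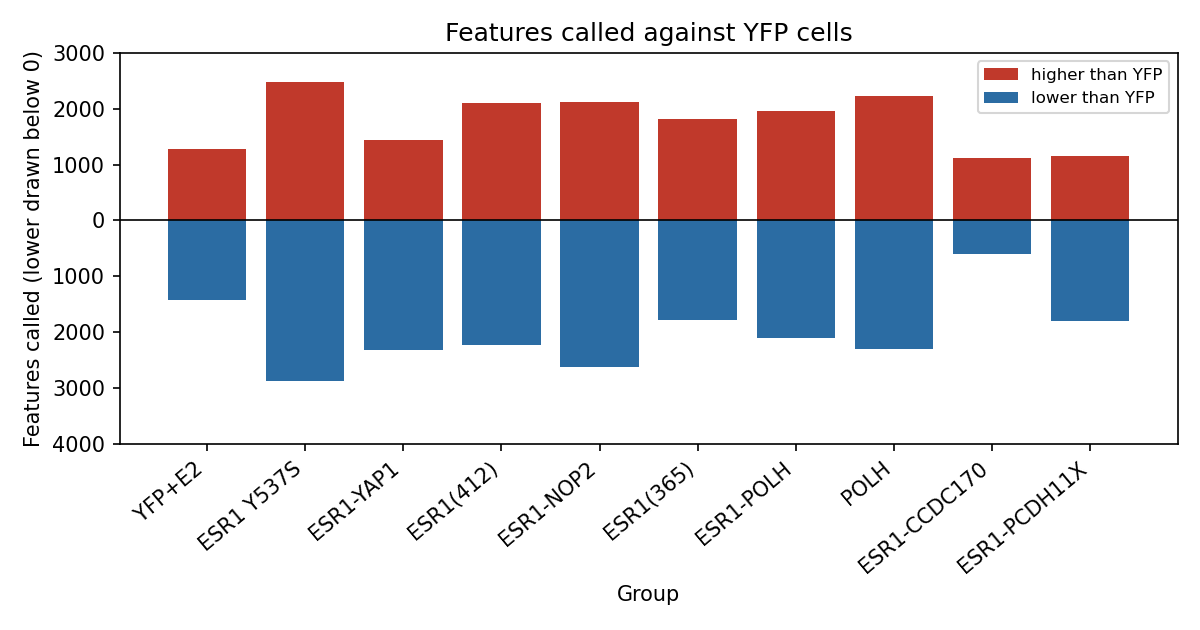
Number of features that rose (red, above 0) and fell (blue, below 0) against YFP cells in each of the 10 groups. The counts run from 1114 higher and 605 lower in ESR1-CCDC170 to 2480 higher and 2869 lower in ESR1 Y537S.

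The Y537S mutant, which lies in the ligand-binding domain and is known from endocrine-resistant tumours, was profiled without hormone. GJA1, the gene of the gap junction protein connexin 43, rose by 5.45 ± 0.06 (n = 3), NPY1R by 4.65 ± 0.10, TFF1 by 4.16 ± 0.05 (n = 4; limma adjusted p = 6.1e-33), and MYC by 3.11 ± 0.05. The growth factor gene AREG rose by 2.78 ± 0.14 (n = 3), RERG by 2.74 ± 0.10 and PGR by 2.24 ± 0.03 (n = 4). Of the 17 estrogen-induced genes 12 rose and none fell, with a mean of 1.44 (adjusted p = 7.55e-07). ERBB2 (-1.74 ± 0.02), CCNG2 (-1.28 ± 0.04) and TGFB3 (-1.23 ± 0.07) fell. STEAP1 (-3.19 ± 0.02, n = 4) and the melanosomal glycoprotein gene GPNMB (-3.08 ± 0.11, n = 3) were the named genes that fell most.

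In Y537S cells 23 of 32 cell cycle genes rose and none fell (mean 0.81, adjusted p = 4.12e-10), with MYBL2 at 1.16 ± 0.02 and BUB1 at 1.15 ± 0.02. The interferon-response genes ISG15 (1.52 ± 0.02), OAS1 (1.73 ± 0.09), IFI6 (1.18 ± 0.05) and MX1 made up the 4 of 7 measured that rose (adjusted p = 0.0377, and adjusted p = 0.0901 with an estimated correlation). In all, 2480 features rose and 2869 fell. Set directly against estradiol-treated cells, Y537S cells differed in 2749 features, 1436 of them higher. GJA1 was higher by 3.68, OAS1 by 2.43 and MX1 by 2.21, and GPNMB was lower at -2.79 (limma adjusted p = 7.0e-24). The interferon list was higher than after estradiol for 6 of 7 genes (mean 1.44, adjusted p = 8.13e-05), and the cell cycle list for 10 of 32 (mean 0.24, adjusted p = 0.0074). Targets of p53 were higher for 5 of 8 (mean 0.74, adjusted p = 0.000632). For the estrogen-induced list the difference had a mean of 0.18, with 2 genes higher and 3 lower, and did not pass (adjusted p = 0.411).

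In the line with the fusion to YAP1, a transcriptional coactivator of the Hippo pathway, the estrogen-induced list was also higher without hormone. Of its members, TFF1 rose by 4.18 ± 0.08 (n = 3, limma adjusted p = 7.6e-31), in 3 of 3 arrays. MYC (2.43 ± 0.09), PGR (1.19 ± 0.07) and MYB (1.17 ± 0.04) rose too. Outside the list, GJA1 rose by 5.74 ± 0.14, ACOX2 by 3.70 ± 0.19, NPY1R by 3.45 ± 0.10 and the Wilms tumour gene WT1 by 3.07 ± 0.12, each in 3 of 3 arrays. The insulin receptor substrate gene IRS1, also outside it, rose by 2.67 ± 0.10. GJA1 rose about as much in ESR1-NOP2 (5.63 ± 0.12), where the list did not pass. Of the 17 estrogen-induced genes 10 rose and none fell, with a mean of 1.02 (adjusted p = 2.08e-07). CCNG2 (-0.93 ± 0.05) and ERBB2 (-0.76 ± 0.09) fell, while BMP7, another gene of the estrogen-repressed list, rose by 1.36 ± 0.16.

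Of 13 luminal marker genes in ESR1-YAP1 cells 2 fell and none rose (mean -0.45, adjusted p = 0.000248), with the epithelial transcription factor gene ELF3 at -1.16 ± 0.10. AP-1 and immediate early genes fell for 5 of 8 (mean -0.51, adjusted p = 0.0035), including JUN (-0.78 ± 0.07) and JUNB (-0.68 ± 0.05). The cell cycle list was higher as a whole (mean 0.27, adjusted p = 0.0042), although only 3 of its 32 genes rose and 1 fell. CCNA2 was among those that rose, at 0.86 ± 0.01. CENPF fell (-0.61 ± 0.05), but no longer passed with quantile normalization (-0.56) or without replicate 3 (-0.58). Only 4 YAP/TEAD target genes were measured, too few for a test, and FJX1 alone rose (0.83 ± 0.03). FJX1 rose alike in ESR1-NOP2 (0.83) and ESR1-POLH (0.90), and the list mean was highest in POLH alone (1.07). In all, 1443 features rose and 2328 fell.

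Against estradiol-treated cells, ESR1-YAP1 differed in 2825 features (1066 higher, 1759 lower), with GJA1 higher by 3.97, the prostaglandin transporter gene SLCO2A1 by 3.30 and ADGRL2 by 2.42. PFKFB3, a glycolytic regulator, was lower at -1.99 (limma adjusted p = 7.7e-18). The estrogen-induced list was lower than after estradiol (mean -0.24, 4 of 17 genes lower and none higher, adjusted p = 0.0258), and so was the cell cycle list (mean -0.30, 7 of 32 lower, adjusted p = 1.07e-05). Interferon genes were higher for 3 of 7 (mean 0.56, adjusted p = 0.0234, and adjusted p = 0.0656 with an estimated correlation), and p53 targets for 3 of 8 (mean 0.48, adjusted p = 0.0168). Against ESR1-NOP2, another fusion, 4692 features differed, with TFF1 higher in ESR1-YAP1 by 4.32, ACOX2 by 3.87 and MYC by 2.97 (limma adjusted p = 6.3e-26 for MYC). The sialyltransferase gene ST3GAL5 (-2.81) and the kinase gene STK32B (-2.56) were lower. In that difference 9 of the 17 estrogen-induced genes were higher and 1 lower (mean 0.86, adjusted p = 0.0197), and 27 of 32 cell cycle genes were higher (mean 0.89, adjusted p = 3.34e-13). Part of the cell cycle difference lay in ESR1-NOP2, where that list averaged -0.62 against YFP.

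**Figure D2:**
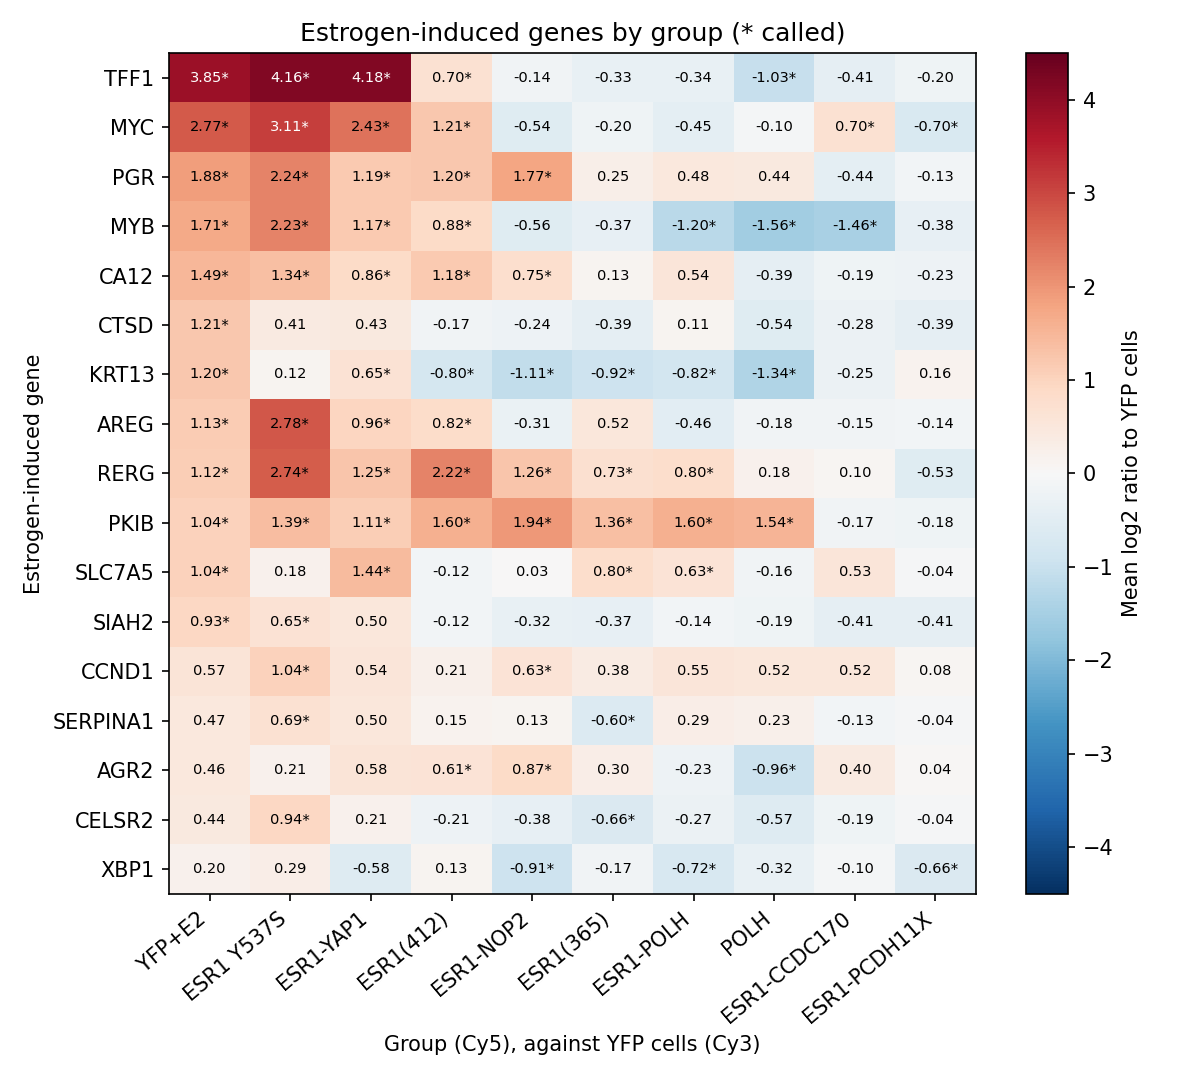
Mean log2 ratio to YFP cells (colour and number) of the 17 measured estrogen-induced genes in the 10 groups; an asterisk marks genes that passed the test. TFF1 stands at 3.85, 4.16 and 4.18 in YFP+E2, ESR1 Y537S and ESR1-YAP1, and at 0.70 or below in the other groups.

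The line with the fusion to the protocadherin gene PCDH11X showed little of that response. MYC fell by 0.70 (SD 0.05, n = 4; limma adjusted p = 1.2e-15), and TFF1 (-0.20 ± 0.20), PGR (-0.13 ± 0.07), MYB (-0.38 ± 0.03) and SIAH2 (-0.41 ± 0.07) did not reach the 1.5-fold minimum. None of the 17 estrogen-induced genes rose and 2 fell, with a mean of -0.22 (adjusted p = 0.0730). The phosphatase genes DUSP4 (-1.60 ± 0.14, n = 3) and DUSP6 (-1.48 ± 0.12, n = 4), which are induced by MAP kinase signalling, fell together with FOS (-1.10 ± 0.04) and SPRY2 (-0.71 ± 0.03). With these, 5 of 8 AP-1 and immediate early genes fell (mean -0.66, adjusted p = 0.0615). Both measured cholesterol synthesis genes fell, SQLE by 0.66 (SD 0.10) and INSIG1 by 0.85 (SD 0.19). The calcium-binding protein gene S100A8 rose by 1.46 ± 0.11 and IRS1 by 1.15 ± 0.08, and the desmosome gene DSP fell to -1.43 ± 0.19.

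In ESR1-PCDH11X cells 1159 features rose and 1795 fell. Against estradiol-treated cells 4667 features differed, and 13 of the 17 estrogen-induced genes were lower and none higher (mean -1.49, adjusted p = 7.44e-09), with ACOX2 at -4.69, TFF1 at -4.05 and MYC at -3.47. The ESR1-YAP1 line was higher than the ESR1-PCDH11X line for 11 of the 17 and lower for none (mean 1.25, adjusted p = 4.02e-07), led by ACOX2 (4.75) and TFF1 (4.38), among 5425 features that differed. GJA1 was higher there by 5.57. Luminal markers were lower in ESR1-YAP1 than in ESR1-PCDH11X (mean -0.37, 4 of 13 lower and 1 higher, adjusted p = 0.0015), with ELF3 at -1.81. From ESR1-NOP2, ESR1-PCDH11X differed in 5789 features, with GJA1 at -5.46 and the transcription cofactor gene EYA2 at 4.30, and 16 of 32 cell cycle genes were higher and none lower (mean 0.63, adjusted p = 2.25e-10). These differences reflect changes in ESR1-NOP2. Against YFP its cell cycle list averaged -0.62, with GJA1 at 5.63 and EYA2 at -4.22.

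In the line with the fusion to NOP2, a nucleolar RNA methyltransferase gene, GJA1 rose by 5.63 ± 0.12, STK32B by 4.07 ± 0.04 and ST3GAL5 by 3.90 ± 0.32 (n = 3, limma adjusted p = 8.1e-21 for ST3GAL5). EYA2 (-4.22 ± 0.08, n = 2), the apolipoprotein gene APOD (-2.80 ± 0.31) and FMO5 (-2.71 ± 0.03) fell most. Members of the estrogen-induced list went both ways. PGR (1.77 ± 0.09), PKIB (1.94 ± 0.10), RERG (1.26 ± 0.07) and CA12 (0.75 ± 0.12) were among 6 that rose, 2 fell, and TFF1 (-0.14 ± 0.06) did not pass. The list's mean was 0.17 and its median -0.14, and the set test did not pass (adjusted p = 0.683). Cell cycle genes fell for 17 of 32 and rose for none (mean -0.62, adjusted p = 3.62e-08), with TOP2A at -1.35 ± 0.12 and CDK1 at -1.03 ± 0.06. In all, 2120 features rose and 2629 fell.

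The fusion with POLH, a translesion polymerase gene, shared several of these changes. ST3GAL5 rose by 3.22 ± 0.17, STK32B by 2.99 ± 0.09 (3.71 with 1 probe per gene) and S100A8 by 2.92 ± 0.11 (n = 3, limma adjusted p = 1.6e-25 for S100A8). LMO4 (-2.88 ± 0.14) and EYA2 (-2.67 ± 0.17) fell. The rises were not particular to the fusions. In POLH alone, without ESR1, S100A8 stood at 3.58, with probe means of 1.60 and 2.04 for ST3GAL5 and 1.48 to 2.67 for STK32B. EYA2 was lower in ESR1-POLH than in POLH alone, at -2.27. Of the estrogen-induced genes 3 rose, PKIB among them at 1.60 ± 0.04, and 3 fell, with MYB at -1.20 ± 0.05; the mean was 0.02, the median -0.14 and the adjusted p 0.824. Of 32 cell cycle genes 9 fell and none rose (mean -0.41, adjusted p = 2.27e-05). In all, 1963 features rose and 2097 fell. Across features, which are not independent replicates, the ESR1-NOP2 and ESR1-POLH group means correlated at r = 0.78 with a covariance of 0.207. Simulated unchanged groups that share 1 reference gave r = 0.74 with a covariance of 0.0258. That r follows from the reference error assumed and the number of arrays, so r alone cannot separate the pair from them. The covariance of the pair lay above the simulated one, for a reference error of the size assumed. ESR1(365) and POLH, which has no ESR1 part, also correlated at 0.78, with a covariance of 0.179.

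POLH alone, without an ESR1 part, served as a control for the overexpressed partner, although no POLH probe could be named to check the construct. Immediate early genes fell sharply. FOS stood at -2.62 ± 0.04 (n = 3; limma adjusted p = 3.9e-33), EGR1 at -2.72 ± 0.04, FOSB at -2.23 ± 0.16 (-1.61 with 1 probe per gene), DUSP6 at -2.26 ± 0.04 and DUSP4 at -3.11 ± 0.08 (n = 2). Of 8 in that list 7 fell and none rose (mean -1.93, adjusted p = 2.27e-05). S100A8 (3.58 ± 0.10) and the Notch ligand gene JAG1 (2.88 ± 0.20) rose. Of the estrogen-induced genes 4 fell, with MYB at -1.56 ± 0.03, TFF1 at -1.03 ± 0.17 and AGR2 at -0.96 ± 0.04, and PKIB alone rose (1.54 ± 0.02, n = 2); the mean was -0.26 (adjusted p = 0.288). Cell cycle genes fell for 8 of 32 (mean -0.41, adjusted p = 3.92e-05), with MCM5 at -0.95 ± 0.04. Interferon genes rose for 4 of 7 (mean 0.67, adjusted p = 0.018, and adjusted p = 0.0597 with an estimated correlation). In all, 2237 features rose and 2306 fell.

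Set against POLH alone, ESR1-POLH differed in 3294 features, 1536 higher and 1758 lower. Immediate early genes were higher for 6 of 8 (mean 1.57, adjusted p = 3.21e-06), with FOS higher by 2.89 (limma adjusted p = 1.4e-29), FOSB by 2.53 (1.804 with 1 probe per gene) and DUSP6 by 2.19. The difference reflects the fall of this list in POLH alone (mean -1.93 against YFP). In ESR1-POLH against YFP, FOS stood at 0.26 and did not pass, and DUSP4 (-1.59) and SPRY2 (-0.86) fell. The steroid sulfatase gene STS was lower at -3.50. Of the estrogen-induced genes 6 were higher and none lower (mean 0.28), which did not pass as a set (adjusted p = 0.104), and no cell cycle gene differed. Luminal markers as a set were lower (mean -0.36, adjusted p = 0.0257, and adjusted p = 0.065 with an estimated correlation). From the POLH line, Y537S cells differed in 6299 features and estradiol-treated cells in 6133. TFF1 was higher than in POLH by 5.19 in Y537S and by 4.88 after estradiol, and ACOX2 by 5.13 and 5.14. All 32 cell cycle genes were higher in Y537S than in POLH (mean 1.22, adjusted p = 4.08e-13), and 29 were higher after estradiol (mean 0.98, adjusted p = 4.74e-12). Estrogen-induced genes were higher than in POLH for 13 of 17 in either group, and interferon genes were lower after estradiol for 6 of 7 (mean -1.20, adjusted p = 0.0034).

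**Figure D3:**
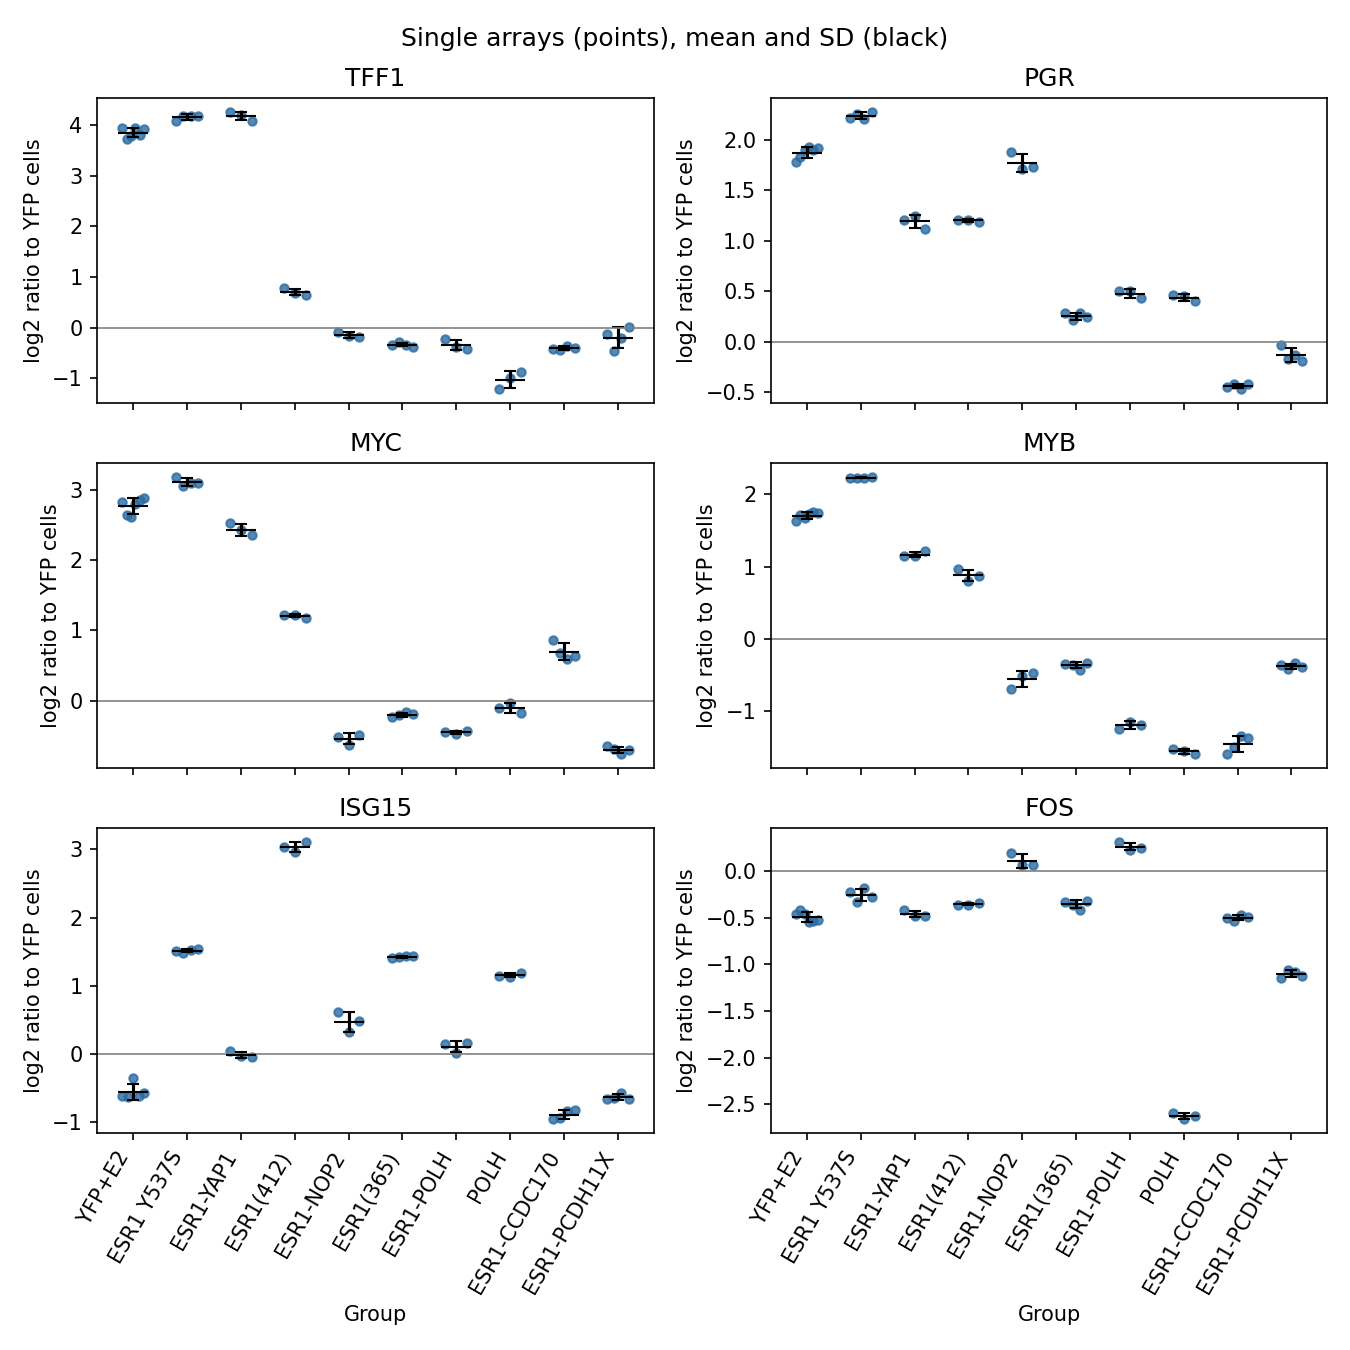
Log2 ratio to YFP cells of TFF1, PGR, MYC, MYB, ISG15 and FOS on every array with a value (points) in the 10 groups, with group mean and SD in black. FOS lies at -2.62 in POLH and at -1.10 in ESR1-PCDH11X, and ISG15 at 3.04 in ESR1(412).

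The ESR1(365) and ESR1(412) constructs, called truncations in the titles, carry no named partner. In ESR1(412) cells the interferon response stood out. LAMP3 rose by 3.48 ± 0.08, IFI6 by 3.22 ± 0.12, IFITM1 by 3.19 ± 0.02, ISG15 by 3.04 ± 0.07 (n = 3; limma adjusted p = 4.9e-30) and OAS1 by 2.83 ± 0.05, and all 7 measured interferon genes rose (mean 2.44, adjusted p = 2.27e-05). Estrogen-induced genes rose for 9 of 17 and fell for 1 (mean 0.56, adjusted p = 0.0050). RERG stood at 2.22 ± 0.03, MYC at 1.21 ± 0.02, PGR at 1.20 ± 0.01 and MYB at 0.88 ± 0.08, and TFF1 reached 0.70 ± 0.07. Cell cycle genes rose for 4 of 32 and fell for 2 (mean 0.11, adjusted p = 0.417), with MKI67 at 1.02 ± 0.07 and MCM5 at -0.93 ± 0.07. ESR1 was higher by 0.58 ± 0.03, just under the 1.5-fold minimum, and passed it with centred arrays (0.592), with 1 probe per gene (0.66) or without replicate 2 (0.594). In all, 2101 features rose and 2229 fell.

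In ESR1(365) cells 6 of 7 interferon genes rose (mean 1.02, adjusted p = 0.0043), with IFI6 at 1.68 ± 0.07, MX1 at 1.48 ± 0.02 and ISG15 at 1.43 ± 0.01 (n = 4; limma adjusted p = 2.5e-23). Cell cycle genes fell for 13 of 32 and rose for none (mean -0.40, adjusted p = 0.000143), including TOP2A (-1.15 ± 0.01), BIRC5 (-1.07 ± 0.04) and CDC20 (-0.94 ± 0.08). Estrogen-induced genes rose for 3 and fell for 3; the mean was 0.03, the median -0.17 and the adjusted p 0.824. TFF1 (-0.33 ± 0.04), PGR (0.25 ± 0.03) and MYB (-0.37 ± 0.04) did not pass. S100A8 rose by 2.99 ± 0.06 and STK32B by 2.81 ± 0.22 (3.64 with 1 probe per gene), and S100P fell to -1.90 ± 0.04. In all, 1812 features rose and 1777 fell.

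Between the pair, 2304 features differed, 1202 of them higher in ESR1(412). The chemokine gene CXCL1 was higher by 3.46 (limma adjusted p = 1.6e-16), OAS2 by 2.10, the NF-kappaB feedback gene TNFAIP3 by 1.94 and IFITM1 by 1.91. SLCO2A1 (-3.17), the syndecan gene SDC2 (-2.79) and the TEAD cofactor gene VGLL1 (-2.12) were lower. All 7 interferon genes (mean 1.42, adjusted p = 2.36e-05), 17 of 32 cell cycle genes (mean 0.51, adjusted p = 9.5e-06) and 7 of 17 estrogen-induced genes (mean 0.53, adjusted p = 0.0015) were higher in ESR1(412), with 1 estrogen-induced gene lower and no interferon or cell cycle gene lower.

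The line with the fusion to CCDC170 had the fewest changed features of the 10 groups in the values as deposited, 1114 higher and 605 lower. With quantile normalization between arrays the counts became 1580 and 1656. Their total of 3236 was still the lowest of the 10 groups, but closer to the next, 3377 in YFP+E2. The Wnt ligand gene WNT11 (1.65 ± 0.24, n = 3), the growth factor-binding protein gene IGFBP3 (1.44 ± 0.12, n = 3) and ITM2A (1.41 ± 0.09, n = 4) rose. The myelin protein gene PMP22 (-1.77 ± 0.44, n = 3) and the interferon-induced gene IFITM1 (-1.52 ± 0.04, n = 4; limma adjusted p = 7.0e-19) fell. MYC rose (0.70 ± 0.12) and MYB fell (-1.46 ± 0.12) as the only members of the estrogen-induced list to pass (mean -0.11, adjusted p = 0.288). Interferon genes fell for 4 of 7 (mean -0.66, adjusted p = 0.0022), with MX1 at -1.06 ± 0.03 and ISG15 at -0.89 ± 0.07. IFI6, another of these, no longer passed without replicate 2 (-0.54). AP-1 and immediate early genes were lower as a set (mean -0.33, adjusted p = 0.0489), with JUNB at -0.80 ± 0.05. The ESR1 probes averaged -0.59 ± 0.05, which met the 1.5-fold minimum and missed it with 1 probe per gene (-0.54) or without replicate 2 (-0.56). In the ESR1 lines other than this and ESR1(412) the mean of these probes did not pass, at 0.19 ± 0.01 in ESR1 Y537S (n = 4), 0.31 ± 0.03 in ESR1-PCDH11X (n = 4), -0.11 ± 0.05 in ESR1-NOP2 (n = 3), -0.19 ± 0.03 in ESR1(365) (n = 4), -0.31 ± 0.06 in ESR1-YAP1 (n = 3) and -0.45 ± 0.03 in ESR1-POLH (n = 3). In POLH, which has no ESR1 construct, the single probes stood at -0.63, -0.41 and -0.48, so a lower value was not particular to ESR1 lines. Whether the constructs carry the sequence these probes read is not given in the sources used here.

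**Figure D4:**
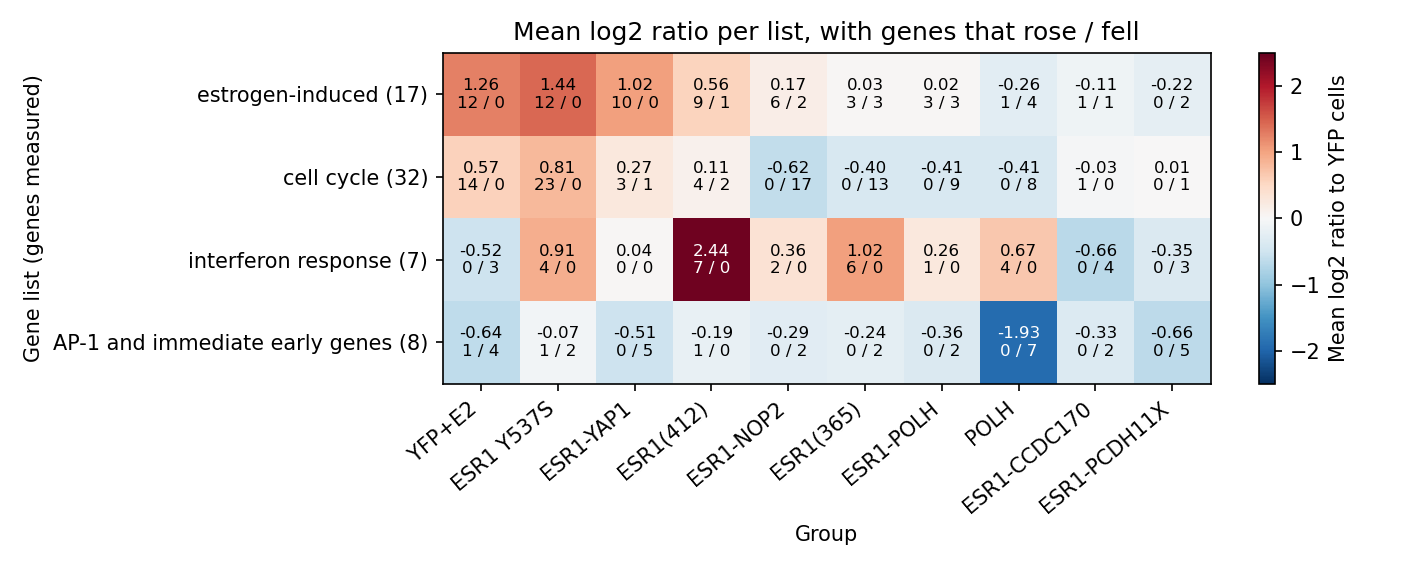
Mean log2 ratio to YFP cells of 4 gene lists in the 10 groups, with the number of genes that rose and fell under each mean. The interferon list reaches 2.44 in ESR1(412), and the AP-1 and immediate early list -1.93 in POLH.

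Across the 10 groups the estrogen-induced list was higher than the other named genes in YFP+E2, ESR1 Y537S, ESR1-YAP1 and ESR1(412), and all 4 calls held with an estimated correlation. PKIB rose in POLH and in every ESR1 line but ESR1-CCDC170 and ESR1-PCDH11X, at 1.94 ± 0.10 in ESR1-NOP2 and 1.36 ± 0.11 (n = 2) in ESR1(365). Of 16 calls of other lists against YFP 14 held, those of the interferon list in ESR1 Y537S and POLH being the exceptions, and of 28 calls in differences between groups 26 held. Counts of estrogen-induced, cell cycle, interferon and immediate early genes adjusted over the list alone equalled those over all features in every group.

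The features that estradiol raised or lowered were compared with those of each line. Of 1280 that rose after estradiol, 853 rose in ESR1 Y537S, 543 in ESR1-YAP1, 324 in ESR1(412), 233 in ESR1-NOP2, 226 in ESR1(365), 201 in ESR1-POLH, 177 in POLH, 152 in ESR1-PCDH11X and 98 in ESR1-CCDC170. Over the 9 lines, independent lists of those sizes would share 58.6 to 130, and simulated unchanged groups with 1 shared reference shared 62.7 to 79.5. For ESR1-CCDC170 the levels were 58.6 and 78.3, both below its 98. Of 1421 that fell after estradiol, 962 fell in ESR1 Y537S, 586 in ESR1-YAP1, 428 in ESR1(412), 372 in ESR1-NOP2, 323 in ESR1-POLH, 293 in POLH, 263 in ESR1(365), 237 in ESR1-PCDH11X and 127 in ESR1-CCDC170. Independent lists would share 35.3 to 167 of these, and simulated groups 64.5 to 81.5. For ESR1-CCDC170 these levels were 35.3 and 77.55, below its 127. The simulated levels rest on an assumed deviation of the reference. Opposite changes were fewer in ESR1 Y537S and ESR1-YAP1, where 28 and 31 features rose that estradiol had lowered, than in POLH with 231. In ESR1-CCDC170, ESR1-POLH and POLH, more features rose that estradiol had lowered (103, 211 and 231) than rose with estradiol (98, 201 and 177). So the shared rises of these lines show no preference for the direction of estradiol. Among features that fell in them, 49, 156 and 172 had risen after estradiol, fewer than the 127, 323 and 293 that had fallen. Whether the overlaps differed between lines was not tested.

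So that the shared reference cancelled, each line minus another line was also correlated, across features, with estradiol arrays of the other suffix style minus a separate line. Features are not independent replicates, so no p is given. The subtracted lines resemble each other, so a line equal to YFP would already give r = 0.35 where ESR1-NOP2 was subtracted and 0.39 where POLH was. These levels, computed after the correlations were seen, mean that r by itself does not measure similarity to estradiol. The correlation was 0.49 for ESR1-YAP1 against a level of 0.35, and 0.44 for ESR1 Y537S (0.43 to 0.45 over its 4 arrays) against 0.39. ESR1-PCDH11X gave 0.32 and ESR1-CCDC170 0.35, both below their levels of 0.35 and 0.39, and ESR1(412) gave 0.09 against 0.39. With the other comparator ESR1-YAP1 moved to 0.57 and ESR1-PCDH11X to 0.39 against a level of 0.46, and ESR1 Y537S to 0.45, ESR1-CCDC170 to 0.32 and ESR1(412) to 0.03 against a level of 0.38. ESR1-NOP2 and ESR1-POLH served as each other's comparator, so their 0.11 and -0.11 are 1 value, and the same holds for ESR1(365) and POLH at 0.10 and -0.10; that value was 0.04 after quantile normalization. All 4 lay below their levels of 0.46, 0.35, 0.39 and 0.38.

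The 6 estradiol arrays spanned both styles of description suffix, numbers and letters, whose meaning is not given in the sources used here. Number-suffixed minus letter-suffixed arrays differed in 195 features, 79 higher and 116 lower (58 and 138 with arrays centred on their medians), of which 3 were named genes: ICAM1 (0.76), PLK1 (0.59) and WNT7B (-0.66; limma adjusted p = 0.017). ICAM1 (0.73) and PLK1 (0.56) no longer passed with centred arrays, nor did ICAM1 without replicate 1, 2, 3, 5 or 6 (0.51 to 0.85) or PLK1 without replicate 3 (0.57) or 5 (0.53). No estrogen-induced gene was among them. Of the other groups 4 carried numbers and 5 letters, so for a difference between those sets the suffix and the line could be separated only through the estradiol arrays.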

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

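No test in this part was chosen only after its result was seen. Of 173 comparisons of the arrays within a group of 4 to 6, 13 set 1 array apart from the others by Dixon's ratio, against 8.65 expected by chance, which sets apart about 1 in 20 groups.

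Replicate 1 of ESR1-CCDC170 had an SD of log2 ratios of 0.573, against 0.340 to 0.350 on the other arrays of its group. Its correlation with the mean of the others was 0.526, against 0.744 to 0.763. Its highest correlation with another group was 0.307, with ESR1(365), which argues against a swapped or wrong label. Over the 7150 features measured on all 37 arrays its correlation was 0.624 and the lowest of the others 0.874, which argues against noise confined to probes that other arrays leave blank. No biological explanation was tested, and without this array 1413 features passed in ESR1-CCDC170, compared with 1719 with it.

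Single arrays stood apart in 3 more groups of 4. In ESR1(365), replicate 1 gave 1.795 for IFI6 (others 1.64 to 1.66), 0.50 for CCND1 (others 0.34 to 0.35) and a correlation with the other arrays of 0.914 (others 0.937 to 0.940), and replicate 3 gave 0.68 for SLC7A5 (others 0.82 to 0.85). In ESR1-PCDH11X, the AP-1 and immediate early list averaged -0.48 on replicate 4 and -0.69 to -0.65 on the others. In ESR1 Y537S, TFF1 stood at 4.09 on replicate 1 (others 4.18 to 4.19), MAD2L1 at 1.26 on replicate 4 (others 1.20 to 1.21), and the cell cycle list at a mean of 0.85 on replicate 3 (others 0.80). Among the 6 estradiol arrays, ADRA2A was 3.22 on replicate 6 (others 3.56 to 3.68), NPY1R 2.48 on replicate 5 (others 2.87 to 3.09), and ISG15 -0.36 on replicate 4 (others -0.63 to -0.57). The explanations of these were not tested.

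Differences between groups were set beside those of other splits of the same arrays into groups of the same sizes, of which only the real split, 1 in each case, reached its own count. The splits cover only variation between arrays, which may be labelling and hybridisation error alone. They cannot exclude chance differences between cell lines or batches. Within that limit the share was under 0.05 for ESR1 Y537S minus POLH (6299 features, highest other split 4142) and YFP+E2 minus POLH (6133, highest other 2260). It was also under 0.05 for ESR1-PCDH11X minus ESR1-NOP2 (5789, highest other 3599) and ESR1-YAP1 minus ESR1-PCDH11X (5425, highest other 3372). So it was for ESR1-YAP1 minus YFP+E2 (2825, highest other 984) and ESR1(412) minus ESR1(365) (2304, highest other 1238). The same holds for ESR1-PCDH11X minus YFP+E2 (4667, highest other 2130) and ESR1 Y537S minus YFP+E2 (2749, highest other 1337), where 100 splits were drawn. The fewest splits among these were 35, and the shares were not adjusted for the number of comparisons. With 3 arrays against 3 the 10 splits are too few for a share under 0.05; there the real values and the highest others were 3294 and 108 for ESR1-POLH minus POLH, 4692 and 66 for ESR1-YAP1 minus ESR1-NOP2, and 195 and 2 for the number-suffixed minus the letter-suffixed estradiol arrays.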

How the results depend on the processing

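The interferon list of ESR1-CCDC170 without replicate 1 was chosen as an alternative only after its result was seen (-0.73 in place of -0.66), and the other alternatives were planned. Quantile normalization moved 50 gene results by more than 1.5-fold, 41 to a smaller and 9 to a larger change. By construction it gives all arrays the same spread, so ratios of wide arrays shrink and those of narrow arrays grow. Against YFP the smaller changes were in ESR1-NOP2, ESR1-YAP1 and ESR1 Y537S, with array SDs of 0.502 to 0.614. The larger ones were in ESR1-CCDC170, ESR1-PCDH11X and YFP+E2, with SDs of 0.340 to 0.471, except 0.573 on replicate 1 of ESR1-CCDC170. Taking 1 probe per gene moved 7, and the cause of that was not tested. No other alternative moved any by as much. With 1 probe per gene THY1 in ESR1-POLH turned from 0.62 to -0.0363 (the cause was not tested), and no other gene result that passed and no correlation changed sign. The estrogen-induced list means of ESR1-POLH (0.02) and ESR1(365) (0.03), which had not passed, became -0.03 and -0.01 on the features measured on all 37 arrays. Of 3982 checks on 350 gene results, 3859 kept their side of the threshold, 97 lost the call without changing sign and 25 gained it; 66 of the losses came from a fold minimum of 2.

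The estrogen-induced list kept its side of the threshold in all 10 groups under every alternative run for it. With 1 probe per gene, with arrays centred on their medians, with only the arrays of the groups compared, with suffix style as a covariate, and with estradiol arrays of 1 suffix style, counts and correlations stayed within their bounds. Titles number the replicates, but arrays of the same number did not resemble each other (median r 0.0144 over 145 pairs of residuals), so replicates were not treated as pairs. With a replicate block all 30 results run kept their value within bounds, and ESR1 in YFP+E2 moved from 0.59 to 0.58 and under the fold minimum. The block was not run for the number-suffixed minus letter-suffixed estradiol arrays, whose replicate numbers do not overlap.

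Restricting the test to the 7150 features measured on all 37 arrays lowered the counts because fewer features were tested. Against YFP they became 1472 in ESR1-NOP2, 1197 in ESR1-POLH, 1042 in ESR1-YAP1, 550 in ESR1-CCDC170, 1100 in ESR1(365), 1298 in ESR1(412), 809 in ESR1-PCDH11X, 1440 in POLH, 1737 in ESR1 Y537S and 899 in YFP+E2. Differences became 983 for ESR1-POLH minus POLH, 2086 for ESR1 Y537S minus POLH, 2050 for YFP+E2 minus POLH, 1452 for ESR1-YAP1 minus ESR1-NOP2, 1787 for ESR1-PCDH11X minus ESR1-NOP2, 1586 for ESR1-YAP1 minus ESR1-PCDH11X, 784 for ESR1-YAP1 minus YFP+E2, 1423 for ESR1-PCDH11X minus YFP+E2, 819 for ESR1 Y537S minus YFP+E2, 765 for ESR1(412) minus ESR1(365) and 40 for the estradiol arrays of both suffix styles. The correlation with estradiol moved to 0.0887 for ESR1-NOP2, -0.0887 for ESR1-POLH, 0.543 for ESR1-YAP1, 0.111 for ESR1(365) and for ESR1(412), 0.330 for ESR1-PCDH11X, -0.111 for POLH and 0.475 for ESR1 Y537S, and the cause was not tested.

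A fold minimum of 2 is stricter by construction, and none is looser. At 2, the counts against YFP were 1446 in ESR1-NOP2, 1157 in ESR1-POLH, 1076 in ESR1-YAP1, 375 in ESR1-CCDC170, 790 in ESR1(365), 1217 in ESR1(412), 444 in ESR1-PCDH11X, 1362 in POLH, 1830 in ESR1 Y537S and 619 in YFP+E2. Differences at 2 were 831 for ESR1-POLH minus POLH, 2636 for ESR1 Y537S minus POLH, 2281 for YFP+E2 minus POLH, 1548 for ESR1-YAP1 minus ESR1-NOP2, 1841 for ESR1-PCDH11X minus ESR1-NOP2, 1729 for ESR1-YAP1 minus ESR1-PCDH11X, 852 for ESR1-YAP1 minus YFP+E2, 1140 for ESR1-PCDH11X minus YFP+E2, 726 for ESR1 Y537S minus YFP+E2, 655 for ESR1(412) minus ESR1(365) and 10 for the estradiol arrays of both styles. With no minimum, the counts were 16767 in ESR1-NOP2, 15906 in ESR1-POLH, 16039 in ESR1-YAP1, 14236 in ESR1-CCDC170, 16814 in ESR1(365), 15985 in ESR1(412), 16580 in ESR1-PCDH11X, 16057 in POLH, 17641 in ESR1 Y537S and 16930 in YFP+E2. Without it the differences were 12303 for ESR1-POLH minus POLH, 14887 for ESR1 Y537S minus POLH, 15637 for YFP+E2 minus POLH, 13435 for ESR1-YAP1 minus ESR1-NOP2, 15157 for ESR1-PCDH11X minus ESR1-NOP2, 15024 for ESR1-YAP1 minus ESR1-PCDH11X, 12204 for ESR1-YAP1 minus YFP+E2, 15994 for ESR1-PCDH11X minus YFP+E2, 13147 for ESR1 Y537S minus YFP+E2, 10083 for ESR1(412) minus ESR1(365) and 5256 for the estradiol arrays of both styles.

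Quantile normalization raised the count in ESR1-CCDC170 to 3236 (1580 higher and 1656 lower, against 1114 and 605) and that between the estradiol arrays of both styles to 370. It widens narrow arrays by construction, but how far this accounts for either rise was not tested. It moved the correlation with estradiol to 0.147 for ESR1-NOP2, -0.147 for ESR1-POLH, 0.495 for ESR1-YAP1, 0.270 for ESR1-CCDC170, 0.0441 for ESR1(365), 0.114 for ESR1(412), 0.266 for ESR1-PCDH11X, -0.0441 for POLH and 0.497 for ESR1 Y537S. With the other comparator the values were 0.0260 for ESR1(412), 0.385 for ESR1-PCDH11X and 0.573 for ESR1-YAP1; the cause was not tested in either case. Centring arrays turned the 79 higher and 116 lower features between the estradiol arrays into 58 and 138. The balance of higher and lower features turned in 6 more comparisons, and the cause was not tested. Quantile normalization gave 1880 higher and 1965 lower in ESR1(365), 2636 and 2610 in ESR1 Y537S minus POLH, 1969 and 1851 in ESR1-YAP1 minus ESR1-NOP2, 2717 and 2693 in ESR1-PCDH11X minus ESR1-NOP2, and 1098 and 1119 in ESR1(412) minus ESR1(365). Centring gave 2337 and 2210 in POLH, and 2989 and 2751 in ESR1-PCDH11X minus ESR1-NOP2.

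Leaving out each array in turn left 257 results within their bounds and moved 14, all of them correlations, with ranges of 0.105 to 0.113 for ESR1-NOP2, -0.113 to -0.105 for ESR1-POLH and 0.483 to 0.491 for ESR1-YAP1. Probe intensities over background were not used here, so the signal behind a ratio is unknown, and features with few values on a group's arrays rest on as few as 2.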

Other observations

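The 5 tests of the features shared by the ESR1 lines and of the interferon list were chosen only after the result was seen, whereas the tests of the gene lists were planned.

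Lists without a call against YFP were mostly small. Of the androgen and progesterone response 5 genes were measured (list means -0.21 to 0.07, smallest adjusted p 0.668), of basal markers 13 (0.10 to 0.37, 0.0588), of epithelial genes 10 (-0.31 to 0.04, 0.0519), of hypoxia and glycolysis 8 (-0.12 to 0.25, 0.369), of p53 targets 8 (-0.30 to 0.45, 0.123) and of ribosome biogenesis 5 (-0.19 to 0.39, 0.0624). Too few for a test were 4 estrogen-repressed genes (means from -0.996 in ESR1 Y537S to 0.29 in ESR1-POLH), 4 YAP/TEAD targets (from -1.07 in ESR1 Y537S to 1.07 in POLH), 2 of cholesterol synthesis (from -0.76 in ESR1-PCDH11X to 0.32 in ESR1(412)), 4 mesenchymal genes (-0.19 to 0.61), 3 of the unfolded protein and amino acid stress response (-0.21 to 0.31) and 2 markers of other cell types (0.05 to 0.64). Of the last pair THY1 rose in ESR1(365) (1.17 ± 0.43, n = 4), POLH (0.95 ± 0.02, n = 2), ESR1(412) (0.80 ± 0.50, n = 2) and ESR1-POLH (0.62 ± 0.46, n = 3), 3 of which are among the 4 groups with a higher interferon list, and VWF passed in no group. All 4 calls of THY1 rested on averaging its probes: with 1 probe per gene the values were 0.33, 0.48, 0.30 and -0.04, and none passed. The call also ended in ESR1(412) without replicate 1 (0.45), and in ESR1-POLH without replicate 1 (0.43) or 2 (0.55) and with quantile normalization (0.54).

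Features that passed in the same direction in all 8 ESR1 construct lines numbered 28, of which 8 were higher and 20 lower. Unchanged lines that share 1 deviating reference gave 29 on average in simulation. The size of that deviation was assumed, so these counts cannot show whether a reference accounts for the features. The named genes among them were RAB6B (higher), GSTP1 and BTN3A3 (lower), chosen after their values were seen. Across these features the median size was 1.32 over the 8 lines and 1.33, signed alike, in POLH, which argues against the ESR1 part of the constructs as the whole cause. In YFP+E2 the median was 0.67, against a bound of 0.66, so a gene-specific dye bias or a deviating reference cannot be told apart from the alternatives. A YFP line that differs from every other transfected line is a candidate explanation for the 0.66 by which POLH exceeded YFP+E2, but with 1 control line it stays open.

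The interferon list was higher in ESR1(412), ESR1(365), ESR1 Y537S and POLH, all of which carry letter suffixes, but with an estimated correlation the calls in ESR1 Y537S (adjusted p = 0.0901) and POLH (adjusted p = 0.0597) were lost. A batch marked by the suffix could raise the list on every letter-suffixed array, but letter-suffixed minus number-suffixed estradiol arrays gave -0.13, and the letter-suffixed ESR1-CCDC170 gave a list mean of -0.70 over its arrays. The -0.13 argues against a batch shared by all letter-suffixed arrays. The -0.70 cannot exclude one, since a fall in that line could outweigh it. A deviating reference sample would move every group alike, whereas the list means over arrays ran from -0.70 to 2.53 in ESR1(412). It therefore cannot account for the differences between groups, but an offset added to falls in some lines cannot be excluded. The response of single cell lines to their constructs, or to the transfection, was not tested.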
